A study of Mus musculus with 5 samples.

How the data were processed

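Tumours of genetically engineered mice with pancreatic cancer were measured by droplet single-cell RNA sequencing. Per the labels, tumours were dissociated, dead cells were removed and the remaining cells were loaded on the 10x Genomics platform, with 1 library per tumour. The 5 libraries fall into 3 groups. KPC mice carry a p48-Cre driver, a lox-stop-lox Kras G12D allele and a floxed Trp53 allele. They gave 1 library after solvent and 2 libraries after MRTX1133, a small-molecule inhibitor of KRAS G12D. iKPC mice carry p48-Cre, a tetO Kras G12D transgene, a ROSA rtTA activator and a floxed Trp53 allele, so that doxycycline keeps the transgene on. They gave 2 libraries after doxycycline withdrawal, which turns the transgene off. Mouse line is therefore confounded with withdrawal, and no iKPC library on doxycycline was used here.

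Per the submitters' processing notes, reads were processed with Cell Ranger 7.2 against GRCm38. The version in the file headers differs between libraries, and the annotation release and the setting for reads in introns were not given in the sources used here. The deposited matrices hold raw UMI counts per gene and cell barcode, already restricted to called cells, and these counts were used for every test. The authors also deposited a table per library with mean counts per cluster, a signal scaled to a common total, together with the log2 fold change and the adjusted p-value of each cluster against the rest. Those tables have no map from cells to clusters, so neither the signal nor the log2 values nor the p-values the authors deposited were used for a test. All 32285 gene identifiers were read, and 32158 of them were found in the GRCm38 annotation used here for positions.

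Barcodes were kept with at least 200 genes detected and at most 20% of UMIs from mitochondrial genes, which removed 38 barcodes of solvent 1, 36 and 85 of MRTX1133 1 and 2, and 322 and 207 of withdrawal 1 and 2. Doublets were scored per library with Scrublet as built into scanpy 1.11.5, and the highest scores were removed at a rate of 0.8% per 1000 barcodes. The rate was set by hand because the automatic threshold of Scrublet marked only 4 barcodes in solvent 1, 1 in each MRTX1133 library and 3 in each withdrawal library. This step removed 23, 33, 432, 99 and 125 cells in the same order of libraries. Counts were scaled to 10000 per cell, 2000 variable genes and 30 principal components were taken, and cells of all libraries were clustered together with the Leiden algorithm (leidenalg 0.10.2, 15 neighbours, resolution 1) without batch correction. A cluster was named "X-like" from marker genes fixed beforehand, counted where raised over the median cluster. At least 3 markers of the class, and no fewer than were missing, had to be found. A cluster also stayed unnamed where its 10 leading genes held more markers of another class, or none at low UMIs. Clusters strong in markers of more than 1 class were first split by clustering them again. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

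The library was the unit of replication. UMI counts were summed per library and cell class and tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 after TMM scaling and filterByExpr, with 1 coefficient per group, all 3 groups in the fit and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p below 0.05. A comparison was run where every library of both groups held at least 20 cells of the class. This left out the withdrawal comparisons in epithelial-like cells and every comparison in fibroblast-like cells. Both were run as additions with at least 10 cells per library, chosen after the cell numbers were seen, and solvent 1, with 5 fibroblast-like cells, entered no fibroblast comparison. The lone solvent library was assumed to vary like the libraries of the other groups. All p-values measure the spread between these samples of 1 tumour each. A fit without 1 library takes its spread from the group that keeps 2 libraries, with 1 residual degree of freedom. For MRTX1133 against solvent without an MRTX1133 library, that group is withdrawal, so neither compared group shows a spread. For withdrawal against solvent without a withdrawal library, that group is MRTX1133, and the same holds.

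Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a class. They were mitogen-activated protein kinase (MAPK) output, proliferation, major histocompatibility complex (MHC) class I, MHC class II, interferon response, myeloid-recruiting cytokines, glycolysis, ductal or classical epithelial identity, acinar identity, mesenchymal transition and dissociation stress. Others covered lipid-associated macrophages, complement or tissue-resident macrophages, inflammatory macrophages, inflammatory monocytes, neutrophil maturation, T cell effector function, exhaustion, regulatory T cells, naive or memory T cells, and fibroblast states (myofibroblastic, inflammatory, antigen-presenting, extracellular matrix). Every camera call reported here was lost when the correlation was estimated instead, and that p is given beside it. The sex-linked genes Xist, Ddx3y, Uty, Kdm5d and Eif2s3y were read per library. Group means carry the SD over libraries, log2 fold changes carry the SE of the fit, and CPM values are TMM-scaled sums, except that those of Kras, its neighbours, Trp53 and the sex-linked genes are UMIs per 1000000 without scaling. Shares have exact binomial 95% intervals and pooled counts exact Poisson intervals, which cover counting error only. Where a gene had no UMI in a group, the fold is a lower bound against a floor of 3 UMIs summed over the group. Where it had 1 to 3 UMIs, the ratio is given with its counting interval. These bounds and ratios come from UMIs pooled over a group without TMM scaling, so they differ from quotients of the CPM values.

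Genes were named by a fixed rule: up to 12 higher and 12 lower genes per class and comparison with the largest change among called genes whose libraries did not overlap, and up to 4 called members of each list, or up to 3 uncalled members as values. Model names, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes were left out. The same rule left out genes that free RNA could bring, and this was read as any gene at least 4 times higher in CPM in another class of the libraries where it was higher. Fewer than 5 eligible genes were filled up to 5 with the smallest p-values, as values. Kras, Trp53 and the sex-linked list were reported for every library.

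The gene test was checked on simulated counts drawn from the real means and library sizes, with 200 genes changed. In neutrophil-like cells (11213 genes), MRTX1133 against solvent, 2.99% of genes changed 2-fold, 47.8% of those changed 4-fold and 81.8% of those changed 8-fold were recovered. In T cell-like cells (7275 genes) the same comparison recovered 0%, 28.4% and 68.2%, and in macrophage/monocyte-like cells (12034 genes) 1.49%, 13.4% and 48.5%. For withdrawal against MRTX1133 in macrophage/monocyte-like cells, 95.5% of genes changed 8-fold were recovered, and 27.3% of all calls fell on unchanged genes. That share of false calls was 15.9% for withdrawal against solvent in the same cells. In epithelial-like sums with at least 10 cells per library it was 16.2% for MRTX1133 and 22.5% for withdrawal against solvent. These 3 comparisons recovered 42.4%, 37.9% and 30.3% of genes changed 8-fold. In the other comparisons with simulated calls the share lay between 3.03% and 9.87%. In epithelial-like cells (10594 genes) none of the genes changed 2-, 4- or 8-fold was recovered at the estimated spread.

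The groups, lists, markers, tests, naming rule and most alternatives were fixed before the data were examined. The alternatives fixed in this way were size factors by relative log expression (RLE), no filter on low counts, DESeq2 1.42.0, a fit of only the 2 groups compared, a stricter cell filter (500 genes, 10% mitochondrial), doublets kept, leaving out each library, other clustering resolutions (0.5 and 2), a filter of 100 genes, a share over non-epithelial cells and, for lists, an estimated correlation and fry. Chosen after the data were seen were sums thinned to the smallest library, the sex of the animals (Xist or Y-linked genes expressed) as a block, leaving out genes 4 times higher in another class, the limit of 10 cells, and leaving out genes called the same way in 3 classes.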

Results

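Single-cell transcriptomes were collected from 5 mouse pancreatic tumours to ask how the tumour microenvironment differed between oncogenic KRAS signalling, its pharmacological inhibition and its genetic withdrawal. After filtering, 1664 cells remained in solvent 1, 1968 and 6874 in MRTX1133 1 and 2, and 3266 and 3728 in withdrawal 1 and 2. Depth was uneven, with 2572708 UMIs in solvent 1, 2739348 and 38822555 in the MRTX1133 libraries and 13134290 and 14787814 in the withdrawal libraries. The median per barcode was 895 UMIs in solvent 1, 936 and 4113 in MRTX1133 1 and 2, and 2316 and 2694 in withdrawal 1 and 2. Comparisons with the solvent library therefore rested on its shallow depth and on n = 1 against n = 2.

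Kras itself (ENSMUSG00000030265, GRCm38 chromosome 6, 145216699 to 145250239, minus strand) was read first in the epithelial-like cells, the class that holds the tumour cells. It stood at 175 CPM (95% Poisson interval 152 to 200) in solvent 1 and was higher in both MRTX1133 libraries, at 1376 (1286 to 1471) and 307 (284 to 331). The withdrawal libraries gave 65.7 (30.1 to 125) and 168 (111 to 245), from only 10 epithelial-like cells each. Over all cells Kras stood at 152 CPM in solvent 1, 513 and 279 in MRTX1133 1 and 2, and 207 and 235 in withdrawal 1 and 2. In MRTX1133 2 only 657 of its 10841 Kras UMIs came from epithelial-like cells. The excess of MRTX1133 2 over solvent 1 was therefore not confined to that class. UMIs do not separate the mutant allele or the transgene from the wild-type allele. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand), the tumour suppressor floxed in both mouse lines, lay between 18.7 CPM (3.85 to 54.6) in withdrawal 2 and 46.2 CPM (37.6 to 56.3) in MRTX1133 2. The withdrawal values rested on 5 and 3 UMIs. Over all cells the sex-linked genes split the libraries within groups. Xist, the RNA that silences an X chromosome, was at 503 CPM in solvent 1, 569 in MRTX1133 2 and 363 in withdrawal 2. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y stood at 133, 136, 23.4 and 72.3 CPM in MRTX1133 1 and at 163, 123, 15.2 and 59.1 CPM in withdrawal 1. In those 2 libraries Xist gave 0.730 CPM and 0, and the count of 0 allows up to 0.281 CPM by the exact interval. In the libraries with Xist, Ddx3y was at 1.56 CPM in solvent 1, 0.361 in MRTX1133 2 and 0 in withdrawal 2, while Uty, Kdm5d and Eif2s3y were at 0.

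In percentage points, the cell composition separated MRTX1133 from solvent and from withdrawal most in neutrophil-like and T cell-like cells. Withdrawal minus solvent was largest in neutrophil-like cells (35.5 points), followed by epithelial-like (-18.8) and T cell-like cells (-16.0). Neutrophil-like cells made up 37.3% (exact binomial 95% interval 35.0 to 39.7) of solvent 1, 8.16% ± 3.27 (SD, n = 2) of the MRTX1133 libraries and 72.8% ± 13.9 (SD, n = 2) of the withdrawal libraries. T cell-like cells stood at 16.9% (15.1 to 18.8) of solvent 1, 45.2% ± 1.17 (SD, n = 2) after MRTX1133 and 0.894% ± 0.164 (SD, n = 2) after withdrawal. Macrophage/monocyte-like cells were at 3.91% (3.03 to 4.95), 4.06% ± 0.0815 and 17.4% ± 8.81 (SD, n = 2) in the same order. Epithelial-like cells were at 19.1% (17.2 to 21.1) in solvent 1, 5.70% ± 5.38 after MRTX1133 and 0.287% ± 0.0268 after withdrawal (SD, n = 2). Fibroblast-like cells were rare, at 0.300% (0.0976 to 0.700), 1.5% ± 1.62 and 0.951% ± 0.776 (SD, n = 2).

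**Figure D1:**
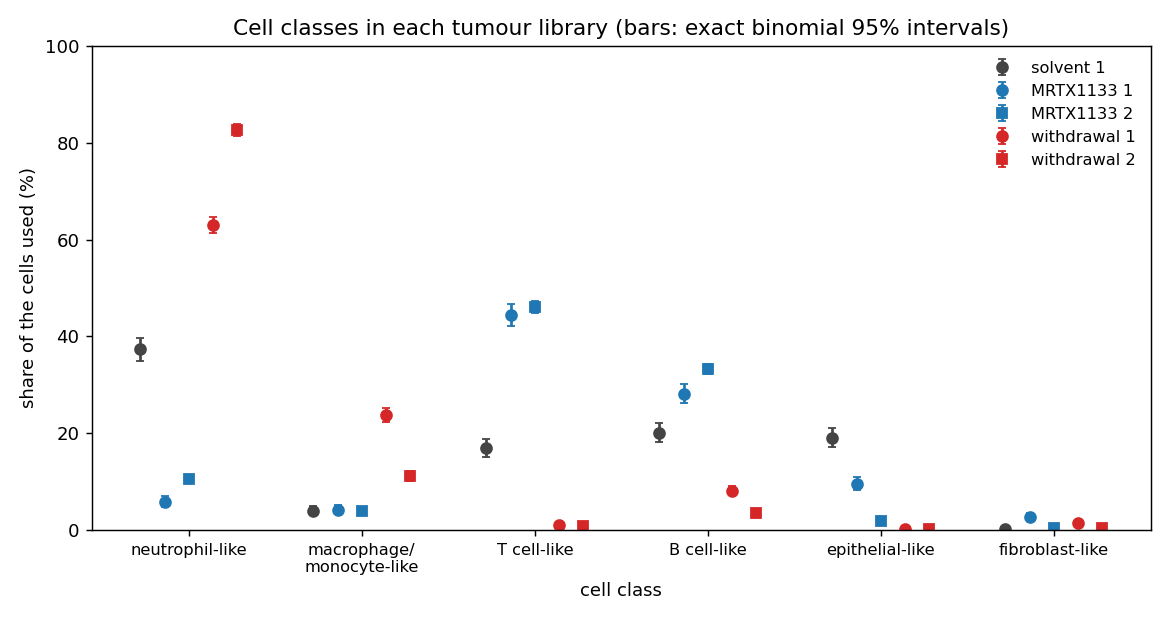
Share of the cells used (y axis, %) in each cell class (x axis) for each tumour library, with grey for solvent, blue for MRTX1133 and red for withdrawal, circles for replicate 1, squares for replicate 2 and bars for exact binomial 95% intervals. Neutrophil-like cells lay at 63.0% and 82.7% in the withdrawal libraries and at 5.84% and 10.5% in the MRTX1133 libraries, and T cell-like cells at 44.4% and 46.1% in the MRTX1133 libraries and at 1.01% and 0.778% in the withdrawal libraries.

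As differences of group means, MRTX1133 stood 29.2 points below solvent in neutrophil-like cells (difference -29.2) and 28.4 points above it in T cell-like cells. Withdrawal stood 64.7 points above MRTX1133 in neutrophil-like cells, 13.4 points above it in macrophage/monocyte-like cells and below it by 44.3 points in T cell-like cells (difference -44.3). With 2 libraries against 1 or 2 against 2 the two-sided exact permutation test cannot go below p = 0.333, and p was 0.333 for these differences. The stricter cell filter, which took the neutrophil-like cells of solvent 1 from 621 to 220, turned the neutrophil-like difference of MRTX1133 from solvent to -14.5 points. The fibroblast-like difference between withdrawal and MRTX1133 (-0.544 points, exact permutation p = 1) changed sign without MRTX1133 1 (0.602) and without withdrawal 2 (0.0046). Leaving out MRTX1133 1 moved the epithelial-like difference between withdrawal and MRTX1133 from -5.41 to -1.60 points, and leaving out MRTX1133 2 moved it to -9.21. The macrophage/monocyte-like excess of withdrawal over solvent was 13.5 points, 7.31 without withdrawal 1 and 19.8 without withdrawal 2. Dissociation and the removal of dead cells can set these shares, and solvent 1 and MRTX1133 1 were the shallow libraries.

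The comparison of MRTX1133 with solvent asked what pharmacological KRAS G12D inhibition was accompanied by. In neutrophil-like cells, single genes of neutrophil granules were higher after MRTX1133. Camp (chromosome 9, 109847379 to 109849617), which encodes the antimicrobial peptide cathelicidin, rose from 1.77 CPM to 5120 and 6076 CPM, a ratio of 2618 in pooled, unscaled counts (counting interval 470 to 1.03e+05; adjusted p = 9.94e-07). Ngp, a granule protein of immature neutrophils, rose by 5.84 ± 0.74 log2 (SE; adjusted p = 3.23e-05), Ltf, which encodes lactoferrin, by 4.28 ± 0.57 (6.06e-05) and Sell, the homing receptor L-selectin, by 3.79 ± 0.49 (3.43e-05). Elane, the gene of neutrophil elastase, was at least 17.9-fold higher (adjusted p = 1.11e-05) and Mpo, myeloperoxidase, at least 9.94-fold higher. Among the genes that fell were Gpnmb, a glycoprotein of phagocytes, with a log2 change of -4.21 ± 0.41 (adjusted p = 1.43e-06), and Atp6v0d2, a subunit of the vacuolar proton pump, with -3.22 ± 0.46 (0.00013). With sums thinned to the total UMIs of the smallest library, the calls of Mpo (adjusted p = 0.11) and Atp6v0d2 (0.24) were lost.

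By list, 6 of 18 neutrophil maturation genes rose and 2 fell, or 6 and 4 adjusted over the list alone, and the list test did not pass (camera adjusted p = 0.29). Camp, Ngp, Ltf and Sell were among those that rose. Of 12 myeloid-recruiting cytokines 4 fell and none rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.14). Among them were Cxcl3 (log2 -2.56 ± 0.57), a chemokine that draws neutrophils, the interleukin Il1a (-1.97 ± 0.46) and the chemokine Cxcl16 (-3.95 ± 0.54), which was over 4 times higher in another class. Interferon response genes split, with 1 of 18 higher and 1 lower (camera adjusted p = 0.29). Of 13 glycolysis genes 1 rose (adjusted p = 0.31 for the list), and of 14 dissociation stress genes 1 rose and 2 fell (adjusted p = 0.94). Cxcl3 lost its call without MRTX1133 2 (adjusted p = 0.39) and by DESeq2 (0.067), and Il1a without withdrawal 1 (0.19) or withdrawal 2 (0.093). Without MRTX1133 2 the remaining MRTX1133 library had no Cxcl16 UMI, so that no fold could be given, and the call held.

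In total 332 genes were higher and 206 lower of 11213 tested, by edgeR at an adjusted p below 0.05. With RLE size factors the split was 431 and 378. Cluster c7 (led by Dedd2, Fnip2 and Hmox1) held 604 of the 621 neutrophil-like cells of solvent 1 and 54 of 115 and 323 of 720 of the MRTX1133 libraries, and cluster c10 (led by Ngp, Camp and Retnlg) held 15 cells of solvent 1 and 49 and 377 of the MRTX1133 libraries. The count of 538 became 1947 without MRTX1133 1, 90 without withdrawal 1 and 115 without withdrawal 2. It was 116 by DESeq2, 207 with only the 2 groups in the fit, 1043 with doublets kept and 67 with thinned sums.

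In macrophage/monocyte-like cells 3 genes passed after MRTX1133. C1qc (chromosome 4, 136889804 to 136893065), a chain of the complement component C1q made by tissue macrophages, rose from 6.59 CPM to 812 and 869 CPM (ratio 96.8 in pooled, unscaled counts, counting interval 17.4 to 3.82e+03; adjusted p = 0.0434). Mmp8, neutrophil collagenase, fell by 4.10 ± 0.44 log2 (adjusted p = 0.0256) and Msantd3 fell by 3.23 ± 0.40 (0.0434). Of 13 complement or resident macrophage genes C1qc alone rose, or 6 adjusted over the list alone. The list passed camera (adjusted p = 0.0019; adjusted p = 0.78 with an estimated correlation), with a median log2 change of 4.64, or 0.00 with genes at 0 set to their bound. Dissociation stress genes passed in the same way with no member called (adjusted p = 0.04, and 0.78 with an estimated correlation). None of 15 lipid-associated macrophage genes passed, but 6 did adjusted over the list alone (camera adjusted p = 0.051). Inflammatory monocyte genes (0.051), inflammatory macrophage genes (0.82), MHC class II (0.18), interferon response (0.45), glycolysis (0.12) and proliferation (0.92) did not pass as lists. Hilpda, a lipid droplet protein, was at least 10.1-fold higher without passing (adjusted p = 0.0594), and it passed by DESeq2 (0.011). It also passed without any 1 of the MRTX1133 or withdrawal libraries, but without an MRTX1133 library 1 library stood against 1.

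In these macrophage/monocyte-like cells edgeR called 3 of 12034 genes, with 1359 at an unadjusted p below 0.05, and DESeq2 called 99. Most of these cells of solvent 1 (60 of 65) were in cluster c16, led by Vcan and Chil3, while the MRTX1133 cells also filled clusters c8 and c17. The count became 823 without MRTX1133 1, 563 without MRTX1133 2, 34 without withdrawal 1 and 38 without withdrawal 2, and Msantd3 lost its call under the stricter cell filter (0.72).

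In T cell-like cells, the genes named first between the MRTX1133 libraries and solvent 1 narrowly missed the threshold. Ccr7, which directs naive T cells to lymph nodes, was higher by 3.27 ± 0.54 log2, at 63.4 CPM in solvent 1 and 736 and 490 CPM after MRTX1133, and Rbm3, an RNA-binding protein, by 2.66 ± 0.43, with an adjusted p of 0.0588 each. At the same p, the phosphatase gene Dusp10 stood at 2.86 ± 0.48, the transcription factor Pou2f2 at -2.10 ± 0.34 and Plcb4 at -2.21 ± 0.37. Naive or memory T cell genes passed as a list with no member called (4 of 7 higher adjusted over the list alone; camera adjusted p = 0.041, and 0.59 with an estimated correlation). S1pr1, the receptor for exit from lymphoid organs, stood at 2.05 ± 0.47 in it (adjusted p = 0.096). Proliferation genes (camera adjusted p = 3.5e-05) and dissociation stress genes (0.0012) passed likewise, each with p = 0.59 at an estimated correlation and none of 19 and 14 members called, of which 3 and 8 were at least 4 times higher in another class. Effector genes (0.17), exhaustion genes (0.77), regulatory T cell genes (0.37) and interferon response (0.068) did not pass, with Ctla4, an inhibitory receptor, at 2.29 ± 0.71. Leaving out MRTX1133 1 or MRTX1133 2 let Ccr7, Rbm3, Dusp10, Pou2f2, Plcb4 and S1pr1 pass, and Ctla4 passed without MRTX1133 2. Those fits set 1 library against 1 and took their spread only from the withdrawal libraries, so they add little support. DESeq2 called all 7 genes.

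Only 1 of 7275 genes was called in T cell-like cells, against 1065 at an unadjusted p below 0.05 and 163 by DESeq2. It was the gene model Gm49359, outside the naming rule and named after its values were seen, at 462 CPM in solvent 1 and 48.8 and 22.0 CPM after MRTX1133 (log2 -3.82 ± 0.45; adjusted p = 0.0122). The count was 344 without MRTX1133 1, 327 without MRTX1133 2 and 0 without withdrawal 1. Cluster c4 held 193 of the 281 T cell-like cells of solvent 1 and 251 and 1024 of the MRTX1133 libraries, and cluster c3, led by Lef1 and Cd8b1, held 78 cells of solvent 1 and 507 and 1147 of the MRTX1133 libraries.

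Epithelial-like cells had 318 cells in solvent 1 and 187 and 130 in the MRTX1133 libraries, and edgeR called 0 of 10594 genes between them. At an unadjusted p below 0.05 there were 821, and DESeq2 called 122. Ranked by p, Prdm8, a histone methyltransferase family member, stood at -8.33 ± 0.75 log2, Asap3 at -6.00 ± 0.59 and Fancl, of the Fanconi anaemia pathway, at -4.41 ± 0.49, each with an adjusted p of 0.33. Reg3b, an antimicrobial lectin of the stressed pancreas, had a ratio of 386 (counting interval 69.1 to 1.53e+04). The gastric-type gene Tff2, a trefoil factor, stood at 3.77 ± 0.66 (adjusted p = 0.353). DESeq2 called Prdm8 (2.3e-21), Asap3 (3e-06), Fancl (0.00035), Reg3b (3e-05) and Tff2 (1e-06). Ductal or classical epithelial genes passed camera (17 measured, none called; adjusted p = 0.0046), as did MHC class II (0.0046), MHC class I (0.011) and dissociation stress genes (5.8e-05), and each had p = 0.57 with an estimated correlation. In the MHC class II list 4 of 5 members, and in the MHC class I list 6 of 9, were at least 4 times higher in another class. MAPK output, the list of direct targets of the pathway downstream of KRAS, did not pass (none of 16 called; median -0.24; adjusted p = 0.29), with Spry1 at 2.07 ± 0.62 and Etv4 at -2.36 ± 0.97. Proliferation (0.29), glycolysis (0.29), interferon response (0.051), myeloid-recruiting cytokines (0.11), acinar (0.27) and mesenchymal transition genes (0.75) did not pass.

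With withdrawal libraries of 10 cells admitted to the fit, 11 genes rose and 84 fell between MRTX1133 and solvent. Tff2 rose by 3.77 ± 0.70 log2 (adjusted p = 0.0325) and Reg1, a regenerating protein of acinar cells, by 5.42 ± 0.82 (0.0137), and Spink1, a trypsin inhibitor, was at least 24.6-fold higher. Prdm8 fell by 8.32 ± 0.71 (0.00257), and Sprr2f, a cornified envelope protein, was at least 227-fold lower. These calls were lost without withdrawal 2 (adjusted p = 0.53 each), where the count of 95 became 0, and with only the 2 groups in the fit (0). The count was 330 without MRTX1133 1, 301 without MRTX1133 2 and 426 without withdrawal 1.

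The comparison of withdrawal with solvent set tumours whose Kras transgene was switched off against solvent-treated tumours of the other mouse line. Neutrophil-like cells of the withdrawal libraries carried more interferon response and glycolysis transcripts. Il1b, the cytokine interleukin-1 beta, rose from 1220 CPM to 18870 and 17040 CPM (log2 3.88 ± 0.61; adjusted p = 3.82e-05), and Siglecf, a lectin of eosinophils and of tumour-associated neutrophils, rose by 4.11 ± 0.58 (1.04e-05). Nr4a2, an immediate early nuclear receptor, was at least 116-fold higher (2.07e-08) and Ifi27l2a, an interferon-induced gene, at least 34.8-fold higher (5.57e-08). Hk2, the first enzyme of glycolysis, rose by 2.07 ± 0.46 (0.0015). The collagenase Mmp8 fell by 4.03 ± 0.33 (1.96e-09) and the inducible heat shock gene Hspa1a by 7.72 ± 0.48 (2.55e-11). Sema3c, a secreted guidance protein, was at least 818-fold lower, and Ntm, a neuronal adhesion gene spanning 968392 bases, had a ratio of 2130 (counting interval 371 to 8.52e+04).

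Interferon response genes rose together, 15 of 18 by the gene test and 16 adjusted over the list alone (median log2 4.34, or 3.04 with bounds). Their camera adjusted p was 3.2e-08, and the adjusted p = 0.28 with an estimated correlation. Of the 18, 5 were at least 4 times higher in another class. Of 13 glycolysis genes 8 rose and none fell, 8 and 0 adjusted over the list alone (camera adjusted p = 0.0061, and 0.28 with an estimated correlation). Neutrophil maturation genes (8 of 18 higher, 3 lower; adjusted p = 0.34), myeloid-recruiting cytokines (3 of 12 higher, 2 lower; 0.34) and dissociation stress genes (9 of 14 higher, 3 lower; 0.094) moved both ways. In the cytokine list Il1a (2.04 ± 0.45) and Cxcl3 (1.56 ± 0.49) rose and Cxcl16 fell (-3.68 ± 0.43). The acinar protease gene Prss2 was at least 4.69-fold higher in these cells (adjusted p = 0.000461). Without withdrawal 1 the calls of Il1a (0.094) and Cxcl3 (0.58) were lost, and Cxcl3 was not called by DESeq2 (0.18).

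In total 1643 genes were higher and 1311 lower of 11213. Most withdrawal cells lay in clusters c0, led by Siglecf and Mmp9, and c1, led by Il23a and Acod1, which held 1 and 0 cells of solvent 1. The count of 2954 became 4479 without MRTX1133 1, 896 without withdrawal 1, 1109 without withdrawal 2 and 713 with sums thinned to the total UMIs of the smallest library. It was 1029 by DESeq2.

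Macrophage/monocyte-like cells of the withdrawal libraries were higher in genes of tissue macrophages and of antigen presentation. Arg1, arginase, a marker of alternatively activated macrophages, rose by 5.89 ± 0.78 log2 (adjusted p = 0.006), and the complement gene C1qb by 5.47 ± 0.79 (0.00906). The mannose receptor gene Mrc1 had a ratio of 19.3 (counting interval 6.61 to 93.7; 0.00906) and C1qc a ratio of 184 (33.0 to 7.25e+03; 0.00249). H2-DMa, which loads peptide on MHC class II, had a ratio of 58.4 (10.5 to 2.3e+03; 0.00464). Ifi27l2a was at least 25.9-fold higher, Hilpda at least 20.1-fold, the chemokine Ccl4 at least 16.2-fold and Retnla, a gene of alternative activation, at least 8.08-fold (0.0141). Vcan (chromosome 13, 89655312 to 89742509), a proteoglycan of monocytes, fell by 4.38 ± 0.50 (0.00249) and Chil3, a chitinase-like protein of monocytes, by 3.80 ± 0.62 (0.0129). Sema3c fell by 8.70 ± 0.60 here as well (8.47e-05). Chil3 lost its call without withdrawal 2 (0.068).

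By list, 6 of 13 complement or resident macrophage genes rose and none fell (9 and 0 adjusted over the list alone; median 7.74, or 0.94 with bounds; camera adjusted p = 0.0001). MHC class II had 5 of 7 higher (6 adjusted over the list alone; 0.0047), interferon response 5 of 19 (8 alone; 0.0012) and inflammatory macrophage genes 2 of 13 (9 alone; 0.038), 7 of the 13 being at least 4 times higher in another class. Proliferation genes passed with none of 19 called and 14 at least 4 times higher in another class (0.02). Each of these 5 lists had an adjusted p = 0.45 with an estimated correlation. Lipid-associated macrophage genes (6 of 15 higher, 1 lower; 0.083), inflammatory monocyte genes (3 of 9 higher, 2 lower; 0.17), dissociation stress (5 of 14 higher, 1 lower; 0.12) and glycolysis genes (none of 13; 0.34) did not pass. In the monocyte list Plac8 rose (ratio 41.8, counting interval 7.50 to 1.65e+03) while Vcan fell.

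Of 12034 genes 265 were higher and 192 lower, and RLE size factors turned that split to 143 and 203. The withdrawal cells lay mostly in cluster c8 (567 and 338 cells, led by Ccr2, Mrc1 and C1qb), which held 1 cell of solvent 1. The count of 457 was 2059 without MRTX1133 1, 1978 without MRTX1133 2, 264 without withdrawal 1, and it was 1943 with only the 2 groups in the fit and 1184 with no filter on low counts.

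**Figure D2:**
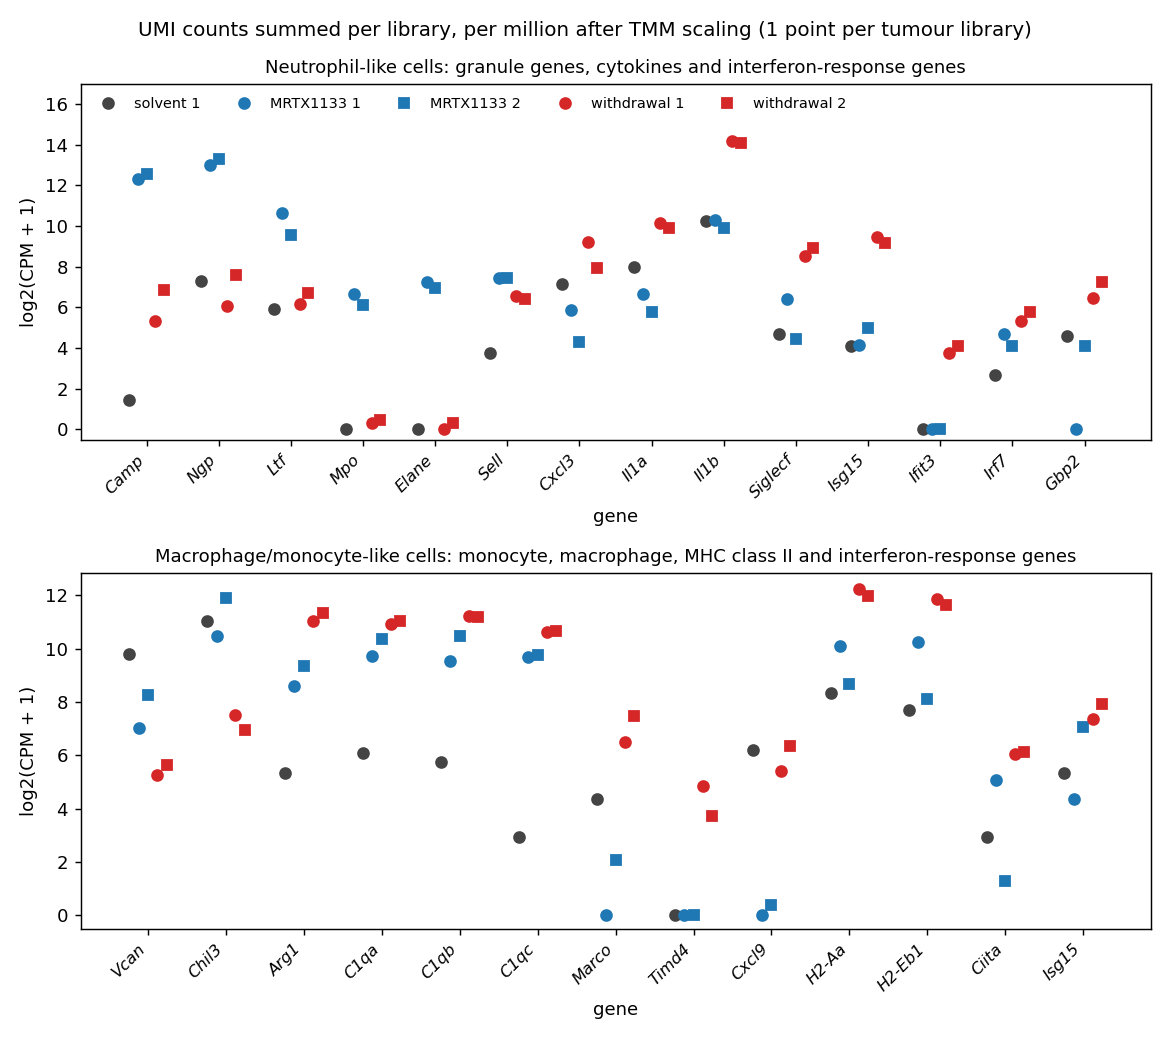
Expression (y axis, log2 of TMM-scaled CPM plus 1) of the genes on the x axis in neutrophil-like cells (upper panel) and macrophage/monocyte-like cells (lower panel), with 1 point per tumour library, grey for solvent, blue for MRTX1133, red for withdrawal, circles for replicate 1 and squares for replicate 2. Camp lay at 5120 and 6076 CPM in the neutrophil-like cells of the MRTX1133 libraries against 39.6 and 114 CPM after withdrawal, whereas Il1b lay at 18870 and 17040 CPM after withdrawal against 1261 and 971 CPM after MRTX1133.

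The few T cell-like cells of the withdrawal libraries, 33 and 29 against 281 in solvent 1, were higher in genes of regulatory T cells and of cell division. Tnfrsf4 and Tnfrsf18, costimulatory receptors of regulatory T cells, each rose by 3.44 ± 0.49 log2 (adjusted p = 0.00384), Ctla4 rose by 4.01 ± 0.74 (0.0104) and the chemokine receptor Ccr8 had a ratio of 31.9 (counting interval 5.49 to 1.28e+03; 0.0106). Ifi27l2a rose by 5.18 ± 0.67 (0.00273). Gzma, a cytotoxic granule protease, was lower with a ratio of 14.1 (3.35 to 126; 0.0452), and Ntm was at least 19.4-fold and Cntnap2 at least 14.9-fold lower. Of 9 regulatory T cell genes 7 rose, 8 adjusted over the list alone (camera adjusted p = 1.5e-05), as did 11 of 19 proliferation genes, 16 adjusted over the list alone (1.8e-08). Exhaustion genes (3 of 9 higher, among them the checkpoint receptors Pdcd1 at 2.20 ± 0.53 and Tigit at 3.07 ± 0.66; 5 alone; 0.022) and interferon response (3 of 11; 5 alone; 0.022) also passed. All 4 had an adjusted p = 0.41 with an estimated correlation. Effector genes (1 of 9 higher, 1 lower; 0.74), naive or memory genes (none of 7; 0.74) and dissociation stress (5 of 14 higher, 2 lower; 0.09) did not pass. Calls were lost without withdrawal 1 for Ctla4 (adjusted p = 0.055), Pdcd1 (0.11), Tigit (0.072) and Gzma (0.12), and without withdrawal 2 for Ccr8 (0.08), Pdcd1 (0.076), Tigit (0.086) and Gzma (0.19).

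In total 428 genes were higher and 220 lower of 7275 in T cell-like cells, most of the withdrawal cells lying in cluster c4 (20 and 14 cells, led by Tnfsf8, Tnfrsf4 and Ctla4), which also held 193 of the 281 cells of solvent 1. Cluster c14.0, led by histone genes and Mki67, held 2 and 10 of the withdrawal cells and none of solvent 1, and the cycling clusters c14.1 and c14.2 held 2 cells each of solvent 1, 1 and 0 of withdrawal 1 and none of withdrawal 2. The count of 648 was 1224 without MRTX1133 1, 1256 without MRTX1133 2, 78 without withdrawal 1 and 140 without withdrawal 2, and it was 1272 with only the 2 groups in the fit.

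In the epithelial-like cells of the withdrawal libraries, 10 each, 10 genes were higher and 76 lower than in solvent 1. Gkn3, a gastrokine, rose by 6.32 ± 0.85 log2 (adjusted p = 0.0225), and Wls, which carries WNT proteins to the cell surface, by 3.92 ± 0.76. Prdm8 was at least 113-fold lower, and Hspa1a (-4.65 ± 0.77) and Hspa1b (-4.29 ± 0.75) fell. Of 14 MAPK output genes none passed and 3 were lower adjusted over the list alone (median -0.49; camera adjusted p = 0.44). These were Dusp6 (-2.31 ± 0.73), Spry2 (-2.10 ± 0.61) and Fosl1 (-2.14 ± 0.62), feedback regulators and a transcription factor induced by MAPK signalling, with adjusted p = 0.163, 0.139 and 0.141 over all genes. Of 17 ductal or classical genes 5 were higher adjusted over the list alone (0.21), with the chloride channel gene Cftr at 3.67 ± 0.76 (adjusted p = 0.056). The count of 86 was 768 without MRTX1133 1, 760 without MRTX1133 2, 333 without withdrawal 1 and 0 without withdrawal 2, where the calls of Gkn3, Wls, Prdm8, Hspa1a and Hspa1b were lost (adjusted p = 0.53). Without MRTX1133 1 or MRTX1133 2, Dusp6 (0.028 and 0.025), Spry2 (0.031 and 0.027), Fosl1 (0.0065 and 0.0085) and Cftr (4.3e-05 and 1.6e-05) passed, as did Cftr without withdrawal 1 (0.00071).

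The comparison of withdrawal with MRTX1133 set genetic withdrawal of KRAS G12D against its pharmacological inhibition, with 2 libraries each but also different mouse lines. Among the classes, neutrophil-like cells had the most called genes. Isg15, an interferon-induced ubiquitin-like protein (chromosome 4, 156199424 to 156200818), was higher after withdrawal, at 714 and 581 CPM against 16.7 and 31.0 CPM (log2 4.48 ± 0.40; adjusted p = 4.31e-09). Il1b rose by 4.02 ± 0.46 (2.16e-07), Il1a by 4.01 ± 0.41 (4.33e-08), the chemokine Cxcl3 by 4.12 ± 0.50 (5.24e-07) and Ptgs2, the inducible cyclooxygenase, by 4.20 ± 0.53 (9.66e-07). Among the lower genes were Camp at -6.18 ± 0.52 (1.86e-09), Ngp at -6.13 ± 0.54, Lcn2 at -4.33 ± 0.42 (1.5e-08) and Elane at a ratio of 724 (counting interval 199 to 6e+03). The protease gene Ctsg was at least 284-fold lower, and Hspa1a fell by 5.59 ± 0.44.

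All 18 interferon response genes rose (18 adjusted over the list alone; median 3.21; camera adjusted p = 9.4e-08, and 0.53 with an estimated correlation), 5 of them at least 4 times higher in another class. Of 12 myeloid-recruiting cytokines 8 rose and none fell, 9 and 0 adjusted over the list alone (0.019, and 0.54 with an estimated correlation), and 5 of the 12 were at least 4 times higher in another class. Neutrophil maturation genes went both ways, 8 of 18 higher and 7 lower, with a median of 0.40 but a mean of -0.38 and a downward camera test (0.61). Glycolysis (9 of 13 higher; 0.08) and dissociation stress genes (9 of 14 higher, 3 lower; 0.08) did not pass as lists. Of the 2 acinar genes measured, Prss2 rose (3.88 ± 0.53), a call lost without MRTX1133 2 (adjusted p = 0.3), and Zg16 fell.

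In total 2399 genes were higher and 2217 lower of 11213. The withdrawal cells lay in clusters c0 and c1, which held 10 and 0 cells of MRTX1133 1 and 9 and 7 of MRTX1133 2. The count of 4616 was 1681 without MRTX1133 2, 1227 without withdrawal 1, 1460 without withdrawal 2, 1407 by DESeq2 and 814 with thinned sums.

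Macrophage/monocyte-like cells were higher after withdrawal in MHC class II genes. Marco, a scavenger receptor (chromosome 1, 120474538 to 120505024), rose from 0 and 3.21 CPM to 88.6 and 178 CPM (log2 5.44 ± 0.57; adjusted p = 0.000706), Retnla by 4.82 ± 0.46 (0.000557) and Cxcl10, a chemokine for activated T cells, by 3.42 ± 0.47 (0.00177). Cxcl9, another ligand of the same receptor, had a ratio of 215 (counting interval 38.5 to 8.52e+03; 0.000706). Cluster c19, with Marco among its leading genes, held 82 and 16 cells of the withdrawal libraries and 0 of either MRTX1133 library. H2-DMb1 rose by 2.69 ± 0.36 (0.00176), Ciita, the master regulator of MHC class II, by 4.38 ± 0.71 and H2-Aa by 2.60 ± 0.54. Chil3 fell by 4.12 ± 0.58 (0.00208) and Sema3c by 6.39 ± 0.54 (0.000309). Without MRTX1133 2 the calls of Cxcl9 (0.064) and Ciita (0.26) were lost, as was that of Ciita by DESeq2 (0.85) and that of H2-Aa without withdrawal 1 (0.15) or withdrawal 2 (0.056). MRTX1133 1 held no UMI of Marco, Retnla or Cxcl10, so that without MRTX1133 2 no fold could be given for them, and their calls held (0.023, 0.0035 and 0.018).

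All 7 MHC class II genes rose (7 adjusted over the list alone; camera adjusted p = 4.9e-05; adjusted p = 0.36 with an estimated correlation). So did 14 of 19 interferon response genes (16 alone; 3e-07), 9 of 13 inflammatory macrophage genes (10 alone; 4.9e-05), 4 of 13 complement or resident macrophage genes (6 alone; 0.0013) and 10 of 19 proliferation genes (13 alone; 4e-05), and each of these 4 lists had p = 0.25 with an estimated correlation. Of the proliferation genes 15 were at least 4 times higher in another class, as were 6 of the inflammatory macrophage genes. Glycolysis genes passed with 3 of 13 higher and 1 lower (0.0014, and 0.47 with an estimated correlation). Lipid-associated genes had 3 of 15 higher and 1 lower, a median of -0.10, a mean of 0.30 and an upward camera test (0.88). Inflammatory monocyte genes had 1 of 9 higher and 2 lower, a median of 0.48, a mean of -0.30 and a downward test (0.56). Dissociation stress genes did not pass (0.57).

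In total 918 genes were higher and 938 lower of 12034. The withdrawal cells lay mostly in cluster c8, which held 37 of 81 cells of MRTX1133 1 but 24 of 275 of MRTX1133 2, where c17, led by Mmp12 and Gpnmb, held 134. The count of 1856 was 4610 without MRTX1133 1, 572 without MRTX1133 2, 224 without withdrawal 1 and 301 without withdrawal 2, and it was 226 by DESeq2 and 62 with thinned sums.

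T cell-like cells after withdrawal were higher in regulatory T cell genes than those after MRTX1133. Foxp3 (chromosome X, 7573644 to 7595245), the lineage factor of regulatory T cells, lay at 236 and 306 CPM against 19.9 and 31.7 CPM (log2 3.33 ± 0.34; adjusted p = 0.000382). Ccr8 rose by 3.99 ± 0.49 (0.000795), the costimulatory receptor Tnfrsf9 by 2.46 ± 0.32 (0.0011), Tigit by 3.07 ± 0.43 (0.00152), Klrg1, a receptor of effector and tissue regulatory T cells, by 5.02 ± 0.46 (0.00016) and Areg, the growth factor amphiregulin, by 4.53 ± 0.36 (6.92e-05). Ccr7 fell by 1.95 ± 0.38 (0.00764) and S1pr1 by 2.08 ± 0.39 (0.00563). Ppp2r3a, a phosphatase subunit, was at least 21.3-fold lower (0.000404). Ccr7 and S1pr1 lost their calls without withdrawal 2 (0.11 and 0.093).

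**Figure D3:**
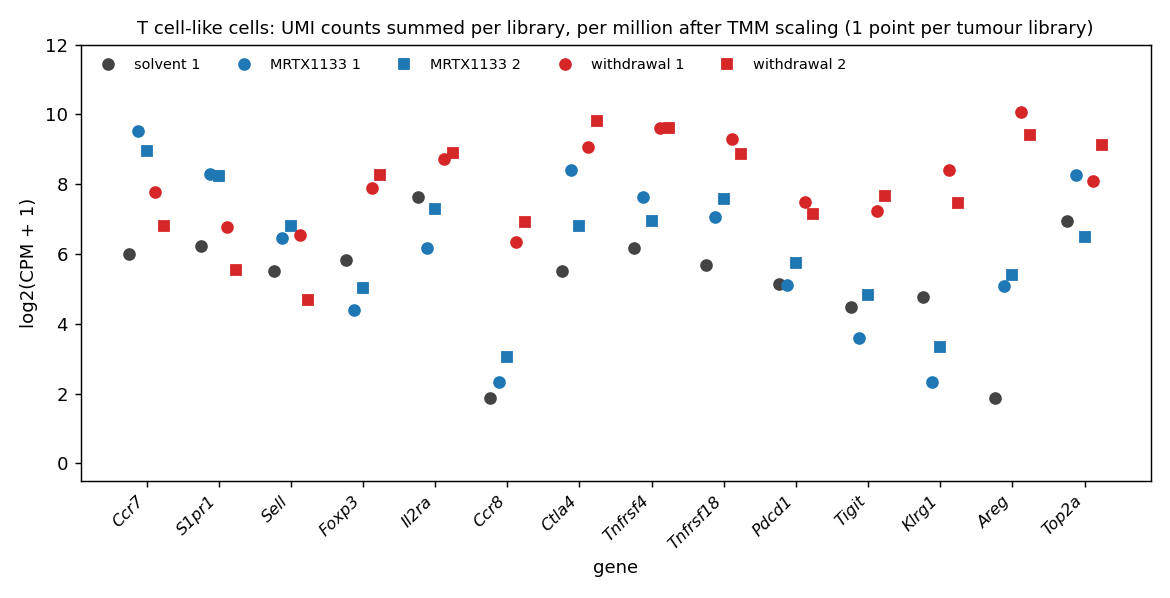
Expression (y axis, log2 of TMM-scaled CPM plus 1) of the genes on the x axis in T cell-like cells, with 1 point per tumour library, grey for solvent, blue for MRTX1133, red for withdrawal, circles for replicate 1 and squares for replicate 2. Foxp3 lay at 236 and 306 CPM in the withdrawal libraries against 19.9 and 31.7 CPM in the MRTX1133 libraries, whereas Ccr7 lay at 218 and 110 CPM after withdrawal against 736 and 490 CPM after MRTX1133 and 63.4 CPM in solvent 1.

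Of 9 regulatory T cell genes 8 rose, 9 adjusted over the list alone (camera adjusted p = 1.5e-06), and of 9 exhaustion genes 6 rose, 6 adjusted over the list alone (0.0026), both with p = 0.27 at an estimated correlation. Proliferation genes rose in 8 of 19 cases, 11 adjusted over the list alone (2.8e-05, and 0.58 with an estimated correlation). Naive or memory genes had 2 of 7 lower, 3 adjusted over the list alone (0.068). Interferon response (4 of 11 higher; 0.099), effector (none of 9; 0.47) and dissociation stress genes (2 of 14 higher, 3 lower; 0.47) did not pass. In total 552 genes were higher and 418 lower of 7275, with withdrawal cells mostly in cluster c4 and MRTX1133 cells mostly in clusters c3, c4 and, for MRTX1133 2, the subclusters of c6. Cluster c14.0 held 9 and 37 cells of the MRTX1133 libraries beside its 2 and 10 cells after withdrawal, and MRTX1133 cells also filled the cycling clusters c14.1 (42 and 7 cells) and c14.2 (29 and 17). The count of 970 was 232 without withdrawal 1, 165 without withdrawal 2 and 502 with thinned sums.

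In the 10-cell epithelial-like sums edgeR called 0 of 9653 genes between withdrawal and MRTX1133, with 1023 at an unadjusted p below 0.05 and 99 by DESeq2. The heat shock genes Hspa1a (-5.35 ± 0.73) and Hspa1b (-5.12 ± 0.71), the glutathione transferase Gsta1 (lower with a ratio of 251, counting interval 44.9 to 9.9e+03), Edn1, the vasoconstrictor endothelin-1 (-4.23 ± 0.61), and Reg1 (-4.35 ± 0.66) had the smallest adjusted p, 0.0605, and all 5 passed without MRTX1133 1, MRTX1133 2 or withdrawal 1 (at most 0.011). None of 14 MAPK output genes passed (median -0.64; camera adjusted p = 0.27). Dissociation stress (0.0053), proliferation (0.035), MHC class II (0.038) and myeloid-recruiting cytokines (0.044) passed downward as lists with no member called, each with p = 0.53 at an estimated correlation. At least 4 times higher in another class were 4 of 4 MHC class II, 8 of 11 proliferation and 5 of 10 cytokine genes, and the proliferation median of -1.41 was -0.06 with bounds. The count was 400 without MRTX1133 1, 174 without MRTX1133 2, 121 without withdrawal 1 and 0 without withdrawal 2.

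Fibroblast-like cells, 52 and 24 after MRTX1133 and 49 and 15 after withdrawal, gave 0 of 4144 genes by edgeR, 485 at an unadjusted p below 0.05 and 42 by DESeq2. Saa3, an acute phase protein, stood at 4.31 ± 0.62 log2 and Il31ra, a cytokine receptor, at 3.08 ± 0.45 (adjusted p = 0.0741 each), and Zc3h7a at 3.83 ± 0.48 (0.0682). All 3 passed without withdrawal 1 (6.7e-05, 0.0025 and 0.0001) or withdrawal 2 (7.9e-06, 0.0046 and 0.00022). Inflammatory fibroblast genes passed upward as a list (14 measured, 1 higher adjusted over the list alone; camera adjusted p = 0.001, and 0.51 with an estimated correlation), with the matrix protein gene Dpt at 1.77 ± 0.45. Extracellular matrix genes passed too (16 measured, none adjusted over the list alone; 0.00052, and 0.62 with an estimated correlation), with Col3a1 at 1.99 ± 0.75, which passed without withdrawal 2 (0.046). Antigen-presenting fibroblast genes (0.0017), myeloid-recruiting cytokines (0.0014) and interferon response (0.0072) passed as well, each with p = 0.45 at an estimated correlation. Myofibroblastic genes did not (12 measured, 1 lower adjusted over the list alone; 0.42). The compared cells sat in different clusters, with c12.0, led by Dcn and Mgp, holding 34 and 15 cells after MRTX1133 and 5 and 2 after withdrawal, and c12.1, led by Col3a1, Sparc and Col1a1, holding 2 and 6 against 31 and 6. The count was 66 without withdrawal 1 and 83 without withdrawal 2.

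Across neutrophil-like, macrophage/monocyte-like and T cell-like cells, 104 genes were higher and 116 lower in withdrawal than in MRTX1133 in all 3 classes, of 6849 genes tested in each. Independent lists of those sizes would share 8.31 and 5.69 genes, but the classes come from the same libraries. Among the lower genes were Hspa1a and Hspa1b of the dissociation stress list. Among the higher genes, 4 were on the interferon response list and 2 on the glycolysis list. Cxcl3 of the myeloid-recruiting cytokines and Cd74 of the MHC class II list were also among them. The same counts for withdrawal against solvent were 47 and 42, where chance overlap gives 1.84 and 0.459. RLE size factors shifted the median of all genes by -0.20 log2 for MRTX1133 against solvent and -0.17 for withdrawal against solvent in macrophage/monocyte-like cells, and by -0.11 for withdrawal against solvent in neutrophil-like cells.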

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

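The tests with thinned sums, with the sex of the animals as a block and with at least 10 cells were chosen only after the results were seen. So were the counts without genes 4 times higher in another class and without genes called the same way in 3 classes. No paired analysis was possible because the replicate numbers follow only the order of the labels and tie no tumour of 1 group to a tumour of another. Of the 182 alternative values of the 14 counts of changed genes, 86 stayed within 1.5 times the value reported and 96 did not. Of the 86, 14 came from leaving out genes 4 times higher in another class. A further 6 came from leaving out genes called the same way in 3 classes. Both settings only removed genes from the lists of calls, with no new test or adjustment. Of the 127 alternative values of the 15 share differences, 109 moved by less than the spread between libraries, 14 moved by more and 4 changed sign. Leaving out 1 of 2 libraries always moves a mean by less than that spread, so those values could only stay or change sign. They make up 9, 10, 10 and 9 of the 109, for MRTX1133 1 and 2 and withdrawal 1 and 2, and say nothing about stability. Of 244 alternative list tests 159 kept their side of the threshold, 79 lost it and 6 gained it. Of the 359 gene results named as called, 138 kept their call in every alternative that could be run and 221 did not keep it in at least 1, and 111 of the 226 named as not called passed in at least 1. The cause was not tested except where stated. Withdrawal comparisons in epithelial-like cells and all comparisons in fibroblast-like cells could not be run at 20 cells, nor could a library be left out of the epithelial-like comparison of MRTX1133 with solvent or a block be added to it. Depth was uneven, the neutrophil-like sums running from 107932 UMIs in MRTX1133 1 to 8512405 in withdrawal 2.

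With no filter on low counts the calls were 456 in epithelial-like, 280 in macrophage/monocyte-like and 239 in T cell-like cells for MRTX1133 against solvent. In macrophage/monocyte-like cells they were 1184 for withdrawal against solvent and 2921 against MRTX1133. In the 10-cell sums they were 382, 566 and 264 in epithelial-like cells (MRTX1133 against solvent, withdrawal against solvent, withdrawal against MRTX1133) and 153 in fibroblast-like cells. DESeq2 called 122, 99, 116 and 163 genes in epithelial-like, macrophage/monocyte-like, neutrophil-like and T cell-like cells for MRTX1133 against solvent. It called 1029 in neutrophil-like cells for withdrawal against solvent, and 1407 in neutrophil-like and 226 in macrophage/monocyte-like cells for withdrawal against MRTX1133. In the 10-cell sums DESeq2 called 209 and 99 for withdrawal against solvent and MRTX1133 in epithelial-like cells and 42 in fibroblast-like cells. RLE size factors moved 1 count by more than 1.5 times, to 809 in neutrophil-like cells for MRTX1133 against solvent.

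With only the 2 groups compared in the fit, the calls for MRTX1133 against solvent were 5 in macrophage/monocyte-like and 207 in neutrophil-like cells, and those for withdrawal against solvent were 1943 in macrophage/monocyte-like and 1272 in T cell-like cells. In the 10-cell epithelial-like sums they were 0, 162 and 14. The stricter cell filter gave 159 in epithelial-like cells, also 159 in their 10-cell sums, and 0 in T cell-like cells for MRTX1133 against solvent. With doublets kept the same comparison gave 196, 18 and 1043 in epithelial-like, macrophage/monocyte-like and neutrophil-like cells. With at least 10 cells per library it gave 95 in epithelial-like cells. Sums thinned to the smallest library gave 300, 33 and 67 for MRTX1133 against solvent in epithelial-like, macrophage/monocyte-like and neutrophil-like cells, 713 in neutrophil-like cells for withdrawal against solvent, and 814, 62 and 502 in neutrophil-like, macrophage/monocyte-like and T cell-like cells for withdrawal against MRTX1133. In the 10-cell sums thinning gave 21 for MRTX1133 against solvent and 80 for withdrawal against MRTX1133 in epithelial-like cells and 1 in fibroblast-like cells. Thinning discards counts, which can lower what the test calls, but some of these counts rose with it. For MRTX1133 against solvent they went from 0 to 300 in epithelial-like and from 3 to 33 in macrophage/monocyte-like cells. For withdrawal against MRTX1133 the 10-cell sums went from 0 to 80 in epithelial-like and from 0 to 1 in fibroblast-like cells. The other thinned counts given here fell.

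Sex, read from Xist and the Y-linked genes, differed within both groups of 2 libraries. With it as a block, which leaves 1 residual degree of freedom, the calls in macrophage/monocyte-like cells were 131 for MRTX1133 against solvent and 994 for withdrawal against MRTX1133. In neutrophil-like cells they were 217, 1614 and 2711 (MRTX1133 against solvent, withdrawal against solvent, withdrawal against MRTX1133), and in T cell-like cells 157 for MRTX1133 against solvent. In the 10-cell sums they were 271, 367 and 218 in epithelial-like cells, in the same order, and 22 in fibroblast-like cells. The other 3 counts stayed within 1.5 times the value reported. Of the named gene results 17 lost their call with the block and 51 gained one.

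Leaving out 1 library at a time gave, for MRTX1133 against solvent, 34 to 823 calls in macrophage/monocyte-like, 90 to 1947 in neutrophil-like and 0 to 344 in T cell-like cells. For withdrawal against solvent it gave 264 to 2059, 896 to 4479 and 78 to 1256, and for withdrawal against MRTX1133 it gave 224 to 4610, 1227 to 5971 and 165 to 1238. In the 10-cell sums the ranges were 0 to 426, 0 to 768 and 0 to 400 in epithelial-like and 0 to 83 in fibroblast-like cells. For withdrawal against MRTX1133 the fitted log2 change of Top2a in macrophage/monocyte-like cells ranged from -0.21 without MRTX1133 2 to 2.86 without MRTX1133 1, and that of Ccl7 in neutrophil-like cells from -0.95 to 7.11 in the same order, the latter fitted against a library at 0 and no bound.

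Among shares in percentage points, the stricter cell filter gave -24.7 for epithelial-like cells (withdrawal minus solvent), -14.5 and 52.5 for neutrophil-like cells (MRTX1133 and withdrawal minus solvent), and 29.8, -20.6 and -50.4 for T cell-like cells (MRTX1133 minus solvent, withdrawal minus solvent, withdrawal minus MRTX1133). The macrophage/monocyte-like difference of MRTX1133 minus solvent, 0.152, became -0.517 with that filter, -0.516 over non-epithelial cells and 0.381 with the filter of 100 genes. The filter of 100 genes gave -18.9 for epithelial-like cells and -15.6 for T cell-like cells (withdrawal minus solvent), and resolution 2 gave -18.8 for epithelial-like cells. Over non-epithelial cells the neutrophil-like difference of MRTX1133 minus solvent was -37.6, and the T cell-like differences were 27.1, -20.0 and -47.1. Leaving out 1 library, the fibroblast-like difference of withdrawal minus MRTX1133 ranged from -1.69 to 0.602, being 0.602 without MRTX1133 1 and 0.0046 without withdrawal 2. The other ranges, for MRTX1133 minus solvent, withdrawal minus solvent and withdrawal minus MRTX1133, were -17.2 to -9.61, -18.84 to -18.80 and -9.21 to -1.60 for epithelial-like cells, and 0.0943 to 0.210, 7.31 to 19.8 and 7.15 to 19.6 for macrophage/monocyte-like cells. For neutrophil-like cells they were -31.5 to -26.8, 25.6 to 45.4 and 54.8 to 74.5, and for T cell-like cells 27.5 to 29.2, -16.1 to -15.9 and -45.2 to -43.5. Fibroblast-like differences against solvent ranged from 0.0487 to 2.34 for MRTX1133 and from 0.102 to 1.20 for withdrawal.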

Other observations

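The tests of free RNA, of a wide Kras copy gain, of an excess of Kras in every class, and of depth, dilution and protocol for the neutrophil-like share were chosen only after the results were seen. With the cell filter as reported, B cell-like cells followed the T cell-like cells across the groups. They made up 20.1% (exact binomial 95% interval 18.2 to 22.1) of solvent 1, 30.7% ± 3.57 (SD, n = 2) after MRTX1133 and 5.80% ± 3.31 (SD, n = 2) after withdrawal. The rise after MRTX1133 depended on the filter. With the stricter one, 237 of 1027 cells of solvent 1, 132 of 1143 of MRTX1133 1 and 2228 of 6685 of MRTX1133 2 were B cell-like. MRTX1133 1 then lay below solvent 1 and MRTX1133 2 above it. The clusters of B cell-like cells differed by library, since cluster c2 held 1917 cells of MRTX1133 2 and 33 of MRTX1133 1, while cluster c11 held 223 and 120 cells of the withdrawal libraries and 1 of solvent 1. NK cell-like cells depended on the resolution of the clustering. At resolution 1 there were 0 of 1664 cells in solvent 1 (up to 0.221% by the exact interval), 0.152% in MRTX1133 1 and 1.69% in MRTX1133 2, with 2, 31 and 67 cells more in cluster c6.6, left unnamed for its NK markers. At resolution 2 there were 2 cells in solvent 1 (up to 0.434% by the exact interval), 32 in MRTX1133 1 (1.63%) and 138 in MRTX1133 2 (2.01%). Plasma cell-like cells were not seen in solvent 1 and stood at 1.02% and 0.611% after MRTX1133. Plasmacytoid dendritic cell-like cells lay at 0.521% in withdrawal 1 and 0.0536% in withdrawal 2. Conventional dendritic cell-like cells stayed between 0.218% in MRTX1133 2 and 1.20% in solvent 1.

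Clusters c19 and c22 were unevenly spread over the groups. Cluster c19, macrophage/monocyte-like and led by Saa3, Alox15, Marco and Cd5l, genes known from large peritoneal or serosal macrophages, held 82 and 16 cells of the withdrawal libraries and none of the other libraries. An unnamed cluster, c22, was led by the adipocyte genes Cfd, Car3, Fabp4 and Adipoq, with 8 cells in solvent 1 and 4 and 14 in the MRTX1133 libraries. No explanation was tested for these clusters.

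Genes called the same way in neutrophil-like, macrophage/monocyte-like and T cell-like cells between withdrawal and MRTX1133 numbered 220. Free RNA from 1 class cannot be told apart from a change of the cells themselves, because the highest of all classes with at least 10 cells exceeded the lowest of the 3 by a median of 4.10 times (bootstrap 95% interval 3.45 to 4.61), short of the 10 times expected of a class that sheds RNA but not clearly below the 4 times set for excluding it, and RNA of cells lost before counting would not show there. In B cell-like cells, which did not define the set, 94.9% (91.1 to 97.4) of 217 genes kept their direction. Of 2710 other genes called in neutrophil-like cells, 63.4% kept the direction they had there. The 217 were selected for the same direction in 3 classes, so the 2 percentages come from unlike selections. The 116 lower genes had a median genomic span 1.51 times that of the other genes tested (permutation p = 0.00314) and the 104 higher genes one of 0.339 times (p = 2e-05, the smallest the permutations can give), which is consistent with a difference in how reads in introns entered the libraries. A change of the withdrawal tumours that reaches every class, through treatment, mouse line or strain, cannot be told apart from that difference, since every withdrawal library is iKPC.

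Kras in epithelial-like cells was 4.49 times higher in MRTX1133 1 than in MRTX1133 2. An excess of Kras in every class of the library was excluded, since the ratio was 0.972 (0.886 to 1.06) in neutrophil-like, T cell-like and B cell-like cells together. Kras was not confined to a few cells of MRTX1133 1, since 152 of its 187 epithelial-like cells held a Kras UMI. No cell held more than 39 of the 865 Kras UMIs. The 19 cells with most Kras relative to their total UMIs held 20.8% of them. That ranking favours cells with few UMIs, so the cells with most Kras UMIs may hold a larger share, and how much of the excess they carry was not tested. The 8 genes within 1000000 bases to each side were not raised as a set. Their median log2 ratio to MRTX1133 2 was 0.0843 (quartiles -0.34 and 0.52) against 2.16 for Kras. This argues against extra copies of the whole region but cannot exclude them. These are RNA values, and all of the genes but Casc1 had only 5 to 25 UMIs in MRTX1133 1. Casc1, near Kras, stood at 202 CPM in MRTX1133 1 against 6.07 CPM in MRTX1133 2. Etfrf1, which lies between Casc1 and Kras, was not raised, at 14.3 and 17.3 CPM. A single gain covering Casc1 and Kras would also hold Etfrf1. But Etfrf1 had 9 UMIs in MRTX1133 1, and RNA levels do not give copy numbers, so these values neither show nor exclude such a gain. A narrower gain of Kras itself was not tested, because no DNA was examined here.

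The neutrophil-like share of all cells was low in both MRTX1133 libraries and high in both withdrawal libraries. Among cells that were not lymphoid it was 69.4% and 86.4% after withdrawal against 59.2% in solvent 1, but among neutrophil-like and macrophage/monocyte-like cells together it was 72.7% and 88.1% after withdrawal, both below the 90.5% of solvent 1. With the stricter cell filter solvent 1 came to 80.0%, withdrawal 1 to 74.0% and withdrawal 2 to 88.9%, so that the direction in withdrawal 2 depended on the filter. Depth did not account for the low share in MRTX1133 1, because solvent 1, of nearly equal depth, differed from it by 31.5 points (17.9 with the stricter filter). Dilution by lymphocytes alone was excluded for MRTX1133 1, whose share stayed 36.9 points below solvent 1 among non-lymphoid cells and 31.9 points below it among neutrophil-like and macrophage/monocyte-like cells (27.3 and 42.6 with the stricter filter). MRTX1133 2 came within 2.19 points of solvent 1 among non-lymphoid cells (57.0% against 59.2%), but lay 18.2 points below it among neutrophil-like and macrophage/monocyte-like cells (72.4% against 90.5%), a proportion that dilution alone would leave unchanged. With the stricter filter that gap was 6.87 points, and among non-lymphoid cells MRTX1133 2 stood above solvent 1 (59.1% against 38.7%), so for MRTX1133 2 dilution cannot be told apart from a change in neutrophils or macrophages. A protocol of the withdrawal libraries that recovers neutrophils better cannot be told apart from withdrawal or mouse line, since barcodes shared with the other libraries numbered 0.0231 per 1000000 pairs against 0.287 within KPC and 2.14 within iKPC, and no withdrawal library in KPC tumours was used here. Within KPC the rate was 1.14 for solvent 1 with MRTX1133 1 but 0.157 and 0.199 for MRTX1133 2 with these, beside 0.157 for solvent 1 with withdrawal 1, so the few shared barcodes do not set MRTX1133 2 with the other KPC libraries. An effect of withdrawal itself stays open and untested.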
